A study of Mus musculus with 6 samples.

How the data were processed

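RNA was measured in 6 libraries from mouse tumours derived from cutaneous squamous cell carcinoma, a cancer of the keratinocytes of the skin. Per the labels' protocols, total RNA was taken from the tumours with a column kit. The genotype label put 3 libraries in the Kindlin-1 wild-type group and 3 in the Kindlin-1 null group. Replicate numbers follow the order of the deposited samples and only name a library.

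The deposited files hold whole-number read counts per Ensembl mouse gene, 1 file per library, with no normalization by the authors. Each file lists 37991 genes and ends in 5 lines for reads assigned to no gene, in the manner of a read counter. Per the submitters' processing notes, the tools TopHat2, Cuffdiff and DESeq2 and the mouse build mm9 were used, with no version and no role stated. The counting program, its settings, its use of strand and the gene annotation are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Reads of near-identical genes, such as granzymes D to G or the heat shock genes Hspa1a and Hspa1b, can be split between copies or dropped, so single members of such families are uncertain. The lines for reads of low quality and for unaligned reads were 0 in all 6 files. Reads outside genes, in more than 1 gene or with several alignments stayed out of library sizes and tests. Reads with several alignments were 34.1%, 35.9% and 40% of all listed reads in wild-type libraries 1 to 3, and 34.9%, 34% and 32.9% in null libraries 1 to 3. Reads in no gene were 7.15%, 8.75% and 12% in the wild-type libraries and 5.84%, 5.55% and 4.63% in the null libraries. Ambiguous reads were between 1.72% and 2.11%.

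Gene symbols were taken from a GENCODE annotation of a later mouse build by Ensembl identifier, and 32919 of the 37991 identifiers (86.6%) matched. Because that build is not the one named by the submitters, no coordinates are given. The later annotation served for symbols, transcript length, GC content and the order of neighbouring genes.

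Depth differed widely. Reads assigned to genes came to 1283566, 161711 and 15529242 in wild-type libraries 1 to 3, and to 1138318, 31487255 and 5226493 in null libraries 1 to 3. A floor of 3 counts stood at 2.34, 18.6 and 0.193 CPM (read counts scaled to the library total) in the wild-type libraries and at 2.64, 0.0953 and 0.574 CPM in the null libraries. Where a group had 1 to 3 reads of a gene left after a library was left out, the ratio of the groups' pooled reads over TMM-scaled totals is given with its exact interval. Floors and Poisson intervals cover counting error only, since the reads carry no molecular identifiers.

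The titles give wild-type libraries 1 and 2 the same mouse number, and null libraries 2 and 3 another shared number, although the file of null library 3 carries a different number in its name. The titles add the letter L or R to the mouse number, and the labels do not give its meaning. If a shared number is 1 animal, each group holds 2 animals, and n = 3 counts libraries. Nothing in the labels says whether libraries with a shared number are separate animals, so p-values measure only the spread between these samples, which may be partly technical. All libraries were thinned to 161711 reads and compared in pairs over genes with a summed count of at least 20. The chi-square per degree of freedom was 1.4 for wild-type libraries 1 and 2 and 1.74 for null libraries 2 and 3, the closest pairs, and between 2.42 and 10.4 for the other 13 pairs. Wild-type libraries 1 and 2 lay closer to null libraries 2 and 3 (2.5 to 3.6) than to wild-type library 3 (5.28 and 6.04). At equal depth the wild-type libraries thus did not form a group of their own. Every pair differed by more than sampling noise, so no file was treated as a copy of another. This does not show whether libraries of a shared number are separate animals. All 6 were kept in the main test, and fits that sum them or give mouse number a random effect stand beside it.

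Differences between null and wild type were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM scaling, default expression filter) and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are null minus wild type, and standard errors (SE) of genes come from the fold change and its F statistic. An SE given with the median of a list is a spread over its genes. It treats them as independent and does not measure variation between tumours. CPM values are TMM scaled and given as mean ± SD over 3 libraries. Of 37 gene lists, those with at least 5 tested members, 31 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over the 31 lists. The same test was run with an estimated correlation, together with fry. For single values the exact permutation test of 3 against 3 libraries cannot go below p = 0.1, two-sided.

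The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Fermt1, Fermt2 and Fermt3. It also names the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold, with a mean log2 CPM of at least 2 and with the 3 null values all on one side of the wild-type values, leaving out predicted genes. From each list it takes up to 4 tested members with the smallest p. Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen.

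Alternatives were DESeq2 1.42.0, limma-voom with quality weights, other scalings (RLE and upper quartile), no filter or a filter of 10 CPM in 3 libraries, libraries of a mouse number summed or given a random effect, a test against a fold change of 1.5, and each library left out in turn. Thinning to equal depth and depth covariates were added after the data were seen. The fit was tested on simulated counts for 11568 genes of the null against wild-type comparison at the real depths. It recovered 24.5% of genes changed by 1 log2 unit, 92.8% of those changed by 2 and 100% of those changed by 3, and 14 of its 165 calls (8.48%) were unchanged genes, a larger share than the threshold of 0.05 names. In a simulated list test over 11585 genes, a list shifted by 1 log2 unit had a camera adjusted p of 1.28e-29, or 0.0142 with an estimated correlation. Of the other lists 1 was also called. The simulated genes were drawn independently, whereas the estimated correlation in the data reached 0.416 (skeletal muscle markers). The simulation therefore gives neither the false-call rate nor the power for lists of correlated genes. The simulated libraries were also independent of each other, with no effect of a shared mouse number, and came from 1 draw. The shares of genes recovered and falsely called may thus not hold if a shared number is 1 animal.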

Results

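RNA sequencing was performed on mouse tumours derived from cutaneous squamous cell carcinoma that either expressed Kindlin-1 (wild type, 3 libraries) or lacked it through knockout (null, 3 libraries). Kindlin-1, encoded by Fermt1, is an adaptor that binds the cytoplasmic tails of beta integrins and takes part in integrin activation. The comparison asked which genes differ in expression between tumours with and without Kindlin-1. Reads assigned to genes ranged from 161711 (wild-type library 2) to 31487255 (null library 2), and 11836 to 20364 genes had at least 1 read. On log2 CPM, wild-type library 2, the shallowest, stood apart on the first principal component (56.9% of the variance).

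Fermt1 (ENSMUSG00000027356) was almost absent from the null tumours. It had 16, 2 and 1040 reads in wild-type libraries 1 to 3 and 0, 2 and 2 reads in null libraries 1 to 3, so the values went with the genotype labels. The mean was 29.9 ± 30.3 CPM in wild type and 0.152 ± 0.211 CPM in null tumours (SD, n = 3), and wild-type library 3 stood at 64.9 CPM against 12.5 and 12.3 CPM in the others. In edgeR's quasi-likelihood test Fermt1 fell 290-fold (log2 fold change -8.18, SE 0.89, Benjamini-Hochberg adjusted p = 0.000297). The 2 reads of wild-type library 2 show what its depth allows for a gene at this level. Over the pooled reads of each group Fermt1 stood at 62.3 CPM in wild type (95% exact Poisson interval 58.6 to 66.2) and at 0.106 CPM in null tumours (0.0288 to 0.271). Without wild-type library 3 the pooled wild-type value was 12.5 CPM (7.38 to 19.7) and the log2 fold change was -6.57 with an edgeR adjusted p of 0.00959, the highest of the 6 fits that each left out 1 library. Without null library 2 or 3, with 2 null reads left, the ratio of wild type to null was 187 (95% exact Poisson interval 51.6 to 1540) or 988 (273 to 8170). The related Fermt2 (ENSMUSG00000037712), which encodes the widely expressed Kindlin-2, rose 2.11-fold from 74 ± 6.41 to 156 ± 47.7 CPM (SD, n = 3; edgeR adjusted p = 0.0398). This call was lost without wild-type library 1, 2 or 3 and without null library 1 or 3, with a highest adjusted p of 0.129 (edgeR, null library 1 left out), and with both pairs of a shared mouse number summed (0.0889) or the wild-type pair alone (0.0711). Fermt3 (ENSMUSG00000024965), encoding the blood-cell Kindlin-3, stood at 75.9 ± 16.2 CPM in wild type and 76.7 ± 5.1 CPM in null tumours (edgeR adjusted p = 0.879).

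**Figure D1:**
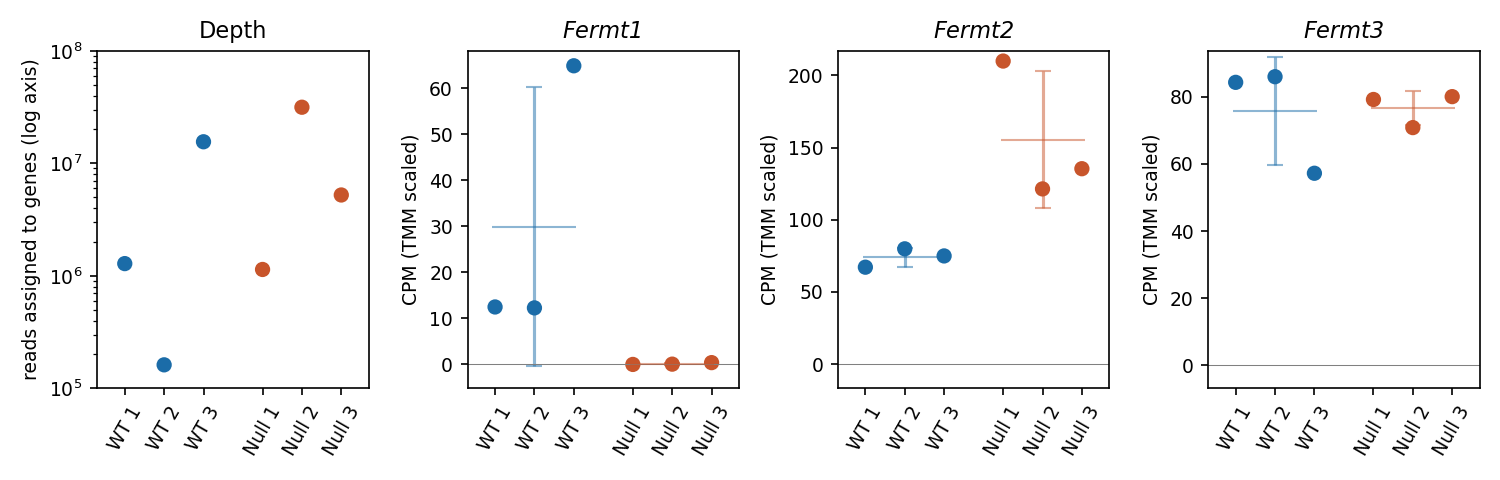
Reads assigned to genes in each library (left, log axis) and TMM-scaled CPM of Fermt1, Fermt2 and Fermt3 in each library. Points are libraries, horizontal lines are group means and bars are 1 SD (n = 3); Fermt1 lay at 12.3 CPM or above in the wild-type libraries and at 0.394 CPM or below in the null libraries.

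Of 11887 genes tested, 688 changed, 269 of them higher and 419 lower in null tumours (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among these, 260 rose and 400 fell by over 2-fold, and 2978 genes had an unadjusted p under 0.05. The 3 null values lay all above or all below the wild-type values for 661 of the 688 genes, and for 3623 (30.5%) of all tested genes. Chance gives 10% if the 6 libraries are independent and 33.3% if each shared mouse number counts as 1 unit, 2 against 2. The count was 281 without wild-type library 3, 179 without null library 1 and 225 without null library 3, and between 519 and 855 without each of the others. With both pairs of a shared mouse number summed, with the wild-type pair summed (both edgeR) and with mouse number as a random effect (limma-voom), 393, 441 and 546 of the 688 genes kept their call and direction. Without wild-type library 1 the higher genes numbered 421. Of 93 genes that passed and were named by the rule, 42 passed in every fit with 1 library left out in which they were tested.

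The genes that rose most in null tumours included a keratin, cytotoxic granule and mast cell proteases, and a collagenase. Krt76, a keratin of suprabasal oral epithelium, had 0 reads in all 3 wild-type libraries and 31 ± 5.52 CPM in null tumours, at least 180-fold higher against a floor of 3 counts over the wild-type group. This bound rested on the depth of wild-type library 3, and was 14.9-fold without it. Fcrl6, an Fc receptor-like protein of lymphocytes, also had 0 wild-type reads and was at least 52.5-fold higher (9.01 ± 5.11 CPM, SD, n = 3), or at least 4.33-fold without wild-type library 3. It was tested in 3 of the 6 fits with 1 library left out and passed in these 3, and its null mean lay under the floor of wild-type library 2 (18.6 CPM). Kera, the corneal proteoglycan keratocan, rose from 0.676 ± 0.631 to 128 ± 65.5 CPM (log2 fold change 6.77, SE 0.54, edgeR adjusted p = 6.85e-05). Ptgfr, the prostaglandin F receptor, rose from 0.208 ± 0.36 to 37.4 ± 14.8 CPM, and its 10 wild-type reads all lay in library 3. The granzymes Gzmg and Gzme, serine proteases of cytotoxic lymphocytes, rose by 5.39 and 4.91 log2 units, to 293 ± 144 and 114 ± 39.9 CPM in null tumours. Ackr4 (5.19), Dsc2 (4.93), Mmp13 (4.76), Ramp3 (4.72), Ctsg (4.64) and Mcpt2 (4.56) followed on the log2 scale. They encode a chemokine scavenger receptor, a desmosomal cadherin, a collagenase, a receptor activity-modifying protein, cathepsin G and a mast cell protease. Without wild-type library 3 Dsc2 (edgeR adjusted p = 0.11), Mmp13 (0.178), Ramp3 (0.068) and Mcpt2 (0.0773) lost their calls, and without null library 1 Ackr4 (0.0501) and Mcpt2 did. Leaving out wild-type library 3 moved the log2 fold changes of Ackr4, Ctsg, Mcpt2 and Gzme to 2.69, 2.5, 2.38 and 3.83, and leaving out wild-type library 1 moved them to 6.88, 6.1, 6.07 and 5.6. Without wild-type library 3 Ptgfr had 0 wild-type reads and was at least 18-fold higher. Kera and Dsc2 had 1, with ratios of 148 (95% exact Poisson interval 26.6 to 5850) and 24.3 (4.34 to 960). The log2 fold change of Mmp13 was then 5.86, and without null library 1 those of Mmp13 and Ramp3 were 3.76 and 4.07. With both pairs of a shared mouse number summed Ackr4 lost its call (edgeR adjusted p = 0.0857). With mouse number as a random effect Dsc2, Fcrl6, Mmp13 and Ramp3 did (limma-voom adjusted p = 0.102, 0.0867, 0.0667 and 0.059).

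The genes that fell most, after Fermt1, included genes of striated muscle. The rule took, among others, Smoc1 (log2 fold change -5.13), Cfd (-4.69), Ttn (-4.58), Retnla (-4.46), ENSMUSG00000093337 (-4.44, no symbol matched), Mylk2 (-4.26), Tnnt3 (-4.2), Jsrp1 (-4.19) and Scn7a (-4.12). Ttn (titin), Mylk2 (skeletal myosin light chain kinase), Tnnt3 (fast skeletal troponin T) and Jsrp1 are muscle genes. Ttn fell from 117 ± 55.4 to 3.68 ± 3.31 CPM (SD, n = 3; SE 0.49, edgeR adjusted p = 0.000289). Smoc1, a secreted calcium-binding matrix protein, fell from 18.5 ± 7.5 to 0.597 ± 0.284 CPM. Cfd, the adipocyte protease adipsin, fell from 26.1 ± 12.1 to 0.533 ± 0.614 CPM. Retnla, a product of alternatively activated macrophages, fell from 32.6 ± 5.74 to 1.06 ± 1.13 CPM. These genes and Fermt1 kept their calls in each fit with 1 library left out in which they were tested, and without null library 2 the log2 fold changes of Ttn and Tnnt3 were -5.69 and -5.08. Retnla, Scn7a and Cfd then had 1, 1 and 2 null reads, and ratios of wild type to null of 178 (95% exact Poisson interval 31.8 to 7040), 120 (21.4 to 4760) and 43.8 (12 to 364). Smoc1 and Mylk2 then had 3 null reads each, and ratios of 41.4 (14.1 to 202) and 22.4 (7.54 to 109). With mouse number as a random effect Retnla and Tnnt3 lost their calls (limma-voom adjusted p = 0.0891 and 0.0518). Without wild-type library 3 ENSMUSG00000093337 stood at -3.71. Values of Fermt1 without single libraries are given with that gene.

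**Figure D2:**
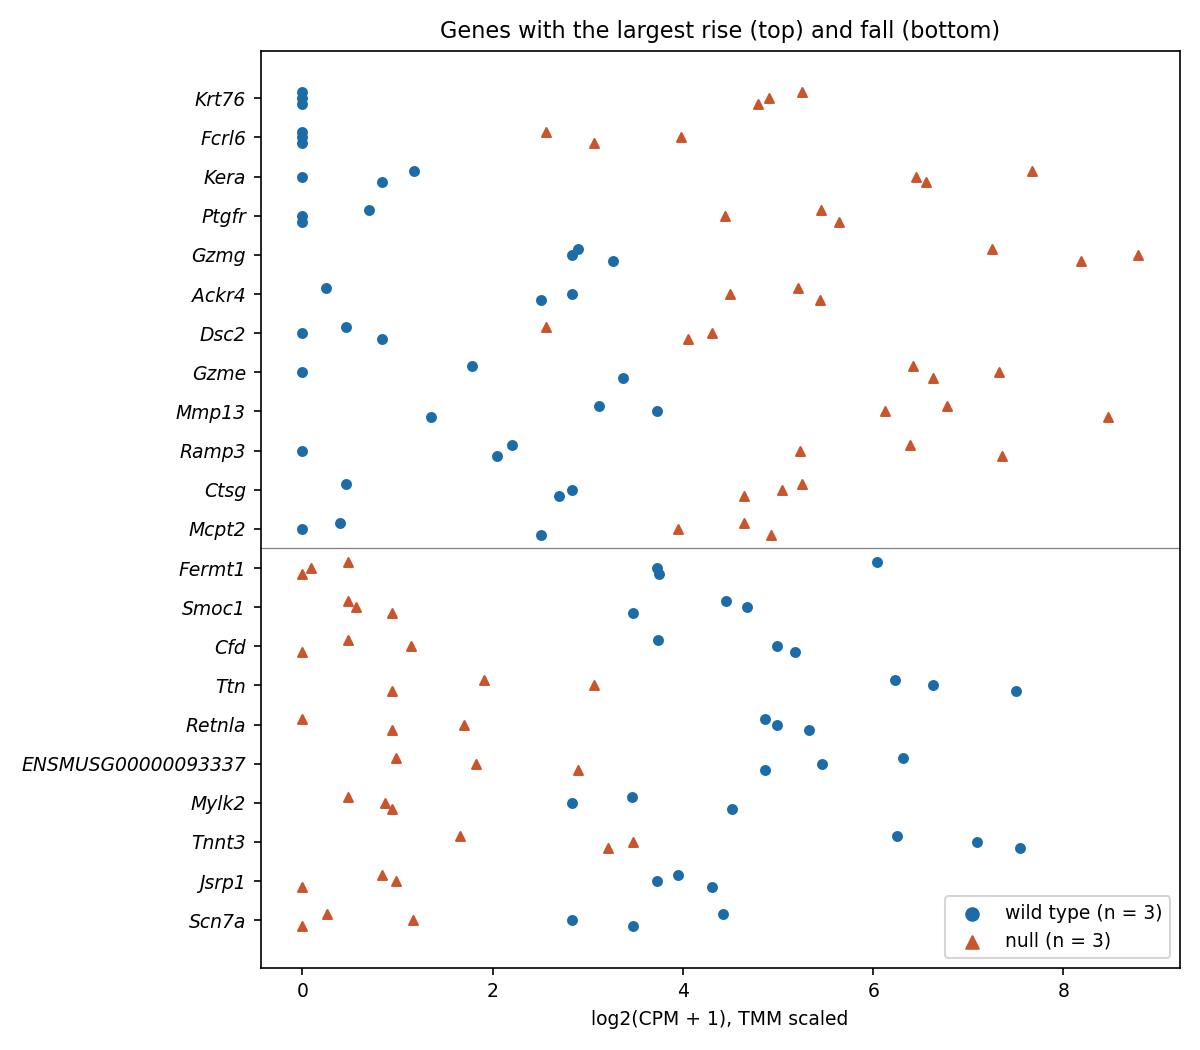
Expression of the 12 genes with the largest rise (top) and of 10 of the 12 with the largest fall (bottom) in each library, as log2(CPM + 1) after TMM scaling. Circles are wild-type libraries and triangles null libraries (n = 3 each); for each gene the 3 null values lie all on one side of the wild-type values.

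The list of skeletal muscle markers was lower as a whole. Of its 20 tested members 16 fell and 0 rose (19 fell when adjusted over the list alone), with a median log2 fold change of -3.31 (camera adjusted p = 7.07e-16, adjusted p = 0.408 with an estimated correlation). Des, the muscle intermediate filament desmin, fell 12.2-fold from 172 ± 92.1 to 14 ± 3.38 CPM, and Ckm, muscle creatine kinase, fell 12.2-fold from 51 ± 24.4 to 4.36 ± 2.79 CPM (SD, n = 3; log2 fold change -4.58 without null library 2). Of 6 tested adipocyte markers 3 fell (3 when adjusted over the list alone; median -1.04, camera adjusted p = 0.00693, adjusted p = 0.408 with an estimated correlation). Besides Cfd these were Lpl (-1.58), whose call was lost without wild-type library 1 and null libraries 1 and 3 (highest edgeR adjusted p = 0.0811), and Car3 (-3.55), lost without wild-type libraries 1 and 2 and null libraries 1 and 3 (highest 0.105). The log2 fold change of Car3 was -2.33 without wild-type library 1, -4.29 without wild-type library 3 and -4.52 without null library 2. Its call was also lost with both pairs of a shared mouse number summed (edgeR adjusted p = 0.243), with the wild-type pair summed (0.0538) and with mouse number as a random effect (limma-voom, 0.424). Without null library 2 the ratio of wild type to null for Cfd, with 2 null reads, was 43.8 (95% exact Poisson interval 12 to 364). Fabp4, the adipocyte fatty acid-binding protein, stood at a log2 fold change of -0.5 (edgeR adjusted p = 0.457). Some further measures, chosen after their values were seen, moved with genotype. Lars2, a mitochondrial leucyl-tRNA synthetase, took 0.473%, 0.799% and 1.85% of the reads in wild-type libraries 1 to 3 and 0.125%, 0.166% and 0.0417% in null libraries 1 to 3 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). Mitochondrial ribosomal RNA took 0.385%, 0.511% and 0.815% against 0.121%, 0.129% and 0.0937%. Both shares ranked the 6 libraries in the same order, so they need not be separate signals.

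Among immune markers, the list of dendritic and mast cell markers and the neutrophil list passed camera as higher in the null tumours, which also carried less of the muscle markers (median -3.31) and lower Lars2 shares. Both list calls were lost with an estimated correlation (camera adjusted p = 0.408 for each). Of 6 neutrophil markers 1 passed singly. Of 13 tested dendritic and mast cell markers 6 rose and 1 fell (7 and 1 when adjusted over the list alone), with a median log2 fold change of 1.39 (camera adjusted p = 0.00426, adjusted p = 0.408 with an estimated correlation). Of the 6 that rose, 5 were mast cell protease or IgE receptor genes, and Ccr7, a chemokine receptor of migrating dendritic cells and chosen after its values were seen, stood just inside the threshold (1.39, edgeR adjusted p = 0.05 after rounding), a call lost with any 1 of the 6 libraries left out (highest 0.205) and with both pairs of a shared mouse number (0.172) or the wild-type pair (0.0653) summed. Cma1, mast cell chymase, rose 3.82-fold from 229 ± 111 to 846 ± 524 CPM, Mcpt4 rose 3.81-fold and Ms4a2, the IgE receptor beta chain, rose 5.12-fold. The calls of these 3 genes were lost without wild-type library 2 or 3 and without null library 1 or 3, with highest edgeR adjusted p values of 0.142, 0.187 and 0.217, and without null library 3 their log2 fold changes were 1.3, 1.17 and 1.57. With mouse number as a random effect all 3 lost their calls (limma-voom adjusted p = 0.238, 0.272 and 0.179). So did Mcpt4 (edgeR, 0.0508) and Ms4a2 (0.075) with both pairs of a shared number summed, and Cma1 (0.0641) and Mcpt4 (0.0714) with the wild-type pair summed. Itgax, the integrin CD11c of dendritic cells, fell 3.38-fold from 34.2 ± 10.4 to 10.3 ± 3.58 CPM, a call lost without wild-type library 3 (edgeR adjusted p = 0.068). Of 6 neutrophil markers 1 rose (4 when adjusted over the list alone; median 1.69, camera adjusted p = 0.0328, adjusted p = 0.408 with an estimated correlation), namely S100a9, which rose 7.16-fold to 25.3 ± 6.37 CPM and lost its call without wild-type library 3 (log2 fold change 1.94, edgeR adjusted p = 0.0634). Of 11 T and NK cell markers 2 rose and 0 fell (3 and 0 when adjusted over the list alone; median 0.29, camera adjusted p = 0.0872, or 0.408 with an estimated correlation), while fry, which does not compare a list with other genes, called the list for direction (adjusted p = 0.00726). Prf1, the pore-forming perforin, rose 12.1-fold from 3.98 ± 4.84 to 48.2 ± 14 CPM (log2 fold change 3.6, or 2.58 without wild-type library 3 and 4.28 without wild-type library 1), and Gzma rose 2.99-fold, a call lost without wild-type library 3 and null library 1 (highest edgeR adjusted p = 0.0887). None of 21 macrophage and monocyte markers passed (0 also when adjusted over the list alone; median -0.03, camera adjusted p = 0.501). Of 13 B and plasma cell markers 2 were tested, too few for a list test, and Cd79b (-0.8) and Cd22 (-0.07) did not pass.

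Among epithelial lists, wound and stress genes passed camera as higher in the null tumours, a call lost with an estimated correlation (adjusted p = 0.408). The muscle markers (median -3.31) and the Lars2 and mitochondrial ribosomal RNA shares were lower in the same null libraries. Of the keratins of that list only Krt17 was tested, with an SE too large to tell its direction (chosen after its values were seen, log2 fold change 0.03, SE 1.77, edgeR adjusted p = 0.994). Of 10 tested wound and stress genes 4 rose and 1 fell (7 and 1 when adjusted over the list alone), with a median log2 fold change of 1.62 (camera adjusted p = 0.01, adjusted p = 0.408 with an estimated correlation). The list call was lost with a filter of 10 CPM in 3 libraries (camera adjusted p = 0.108). Besides S100a9, which the neutrophil list also holds, Fosl1 (3.51), Tslp (1.94) and Cxcl5 (1.32) rose, an AP-1 transcription factor, an epithelial cytokine and a neutrophil chemokine. Fosl1 was tested in 3 of the 6 fits with 1 library left out and lost its call in 2 of them, without wild-type library 1 and null library 1. The call was lost for Tslp without all libraries but wild-type library 2, for Cxcl5 without wild-type libraries 1 and 2 and null libraries 1 and 2, and for S100a9 without wild-type library 3. The highest edgeR adjusted p values of Fosl1, Tslp, Cxcl5 and S100a9 were 0.135, 0.161, 0.16 and 0.0634. Without wild-type library 3 the log2 fold change of S100a9 was 1.94, and Tslp had 2 wild-type reads and a ratio of null to wild type of 7.71 (95% exact Poisson interval 2.12 to 63.9). Fosl1 then had 1 wild-type read and a ratio of 5.78 (1.02 to 230), against a fitted 11.4-fold over all libraries. Its values overlapped between the groups (2.173 ± 3.444 and 5.453 ± 1.85 CPM, SD, n = 3). With mouse number as a random effect Fosl1, Tslp and Cxcl5 lost their calls (limma-voom adjusted p = 0.16, 0.0571 and 0.0853). So did Tslp with both pairs of a shared number summed (edgeR, 0.0833) and Cxcl5 with the wild-type pair summed (0.0628). Of 15 basal keratinocyte and hemidesmosome genes 1 rose and 5 fell (2 and 6 when adjusted over the list alone; median -0.42, camera adjusted p = 0.147). Krt14, a basal keratin, fell 4.1-fold from 36.2 ± 9.49 to 8.6 ± 3.03 CPM (SD, n = 3), whereas the basal keratin Krt15, chosen after its values were seen, rose 4.77-fold from 3.32 ± 3.53 to 19.4 ± 8.1 CPM (edgeR adjusted p = 0.0283). The Krt15 call was lost without wild-type library 3 (log2 fold change 1.56 in place of 2.26, edgeR adjusted p = 0.204) and without null library 1 (0.107). Of 10 epithelial junction genes 1 rose and 2 fell (2 and 2 when adjusted over the list alone; camera adjusted p = 0.951). The desmosomal genes Perp (-1.89) and Pkp1 (-2.47) fell, and Dsc2 rose (4.93). The Dsc2 call was lost without wild-type library 3 (edgeR adjusted p = 0.11), with 1 wild-type read left and a ratio of 24.3 (95% exact Poisson interval 4.34 to 960), and with mouse number as a random effect (limma-voom, 0.102). It was tested in 5 of the 6 fits with 1 library left out. In each of the keratinocyte differentiation list (36 genes) and the list of simple-epithelium keratins (7 genes) 4 members were tested and 0 passed. Krt10 stood at 11.5 ± 0.921 and 9.81 ± 2.79 CPM, and Krt8 at 18.3 ± 17.6 and 21.7 ± 19.3 CPM. Krt8 split by library and not by genotype, with 35.9, 18.4 and 0.624 CPM in wild-type libraries 1 to 3. In null libraries 1 to 3 it stood at 36.9, 0.0317 and 28.3 CPM. The lowest value of each group lay in its deepest library, and the cause was not tested.

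Matrix genes changed in both directions. Of 33 tested fibrillar collagen and matrix genes 4 rose and 9 fell (4 and 14 when adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.00426, adjusted p = 0.481 with an estimated correlation). The list call was lost with all libraries thinned to equal depth (camera adjusted p = 0.294). Fbn1 (fibrillin-1), Col14a1 and Tnc (tenascin C) fell 3.56-fold, 5.41-fold and 3.84-fold, whereas the small proteoglycan Lum (lumican) rose 7.58-fold from 66.9 ± 19.6 to 476 ± 102 CPM (SD, n = 3; edgeR adjusted p = 0.000384). Without null library 2 the log2 fold change of Col14a1 was -3.18 in place of -2.44. Of 20 fibroblast markers 5 rose and 2 fell (6 and 7 when adjusted over the list alone; median 0.19, camera adjusted p = 0.895), with Thy1 lower (-1.62). Of 33 mesenchymal transition genes 3 rose and 5 fell (5 and 8 when adjusted over the list alone; camera adjusted p = 0.595). Of 30 matrix proteases and inhibitors 2 rose and 3 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.785). Mmp3, the protease stromelysin-1, rose 16.5-fold from 84.4 ± 33.4 to 1400 ± 554 CPM, and Serpine2 fell 4.12-fold. Of 19 basement membrane genes 0 rose and 2 fell (3 and 3 when adjusted over the list alone; median -0.06, camera adjusted p = 0.147), Lamb3 (-1.8) and Col7a1 (-2.02). Lamb3 lost its call without wild-type library 3 and null library 3, and Col7a1 without wild-type library 3 and null libraries 1 and 3 (highest edgeR adjusted p 0.0665 and 0.3). The log2 fold change of Col7a1 was -1.1 without wild-type library 3 and -2.94 without null library 2. Its call was also lost with both pairs of a shared mouse number summed (edgeR adjusted p = 0.103), with the wild-type pair summed (0.0595) and with mouse number as a random effect (limma-voom, 0.233). The basement membrane list itself passed without wild-type library 3 (camera adjusted p = 0.0106), without null library 3 (0.029) and with the filter of 10 CPM (0.0404). Of 19 endothelial and pericyte markers 1 rose and 1 fell (1 and 1 when adjusted over the list alone; camera adjusted p = 0.595), namely Lyve1, a lymphatic receptor, 5.56-fold higher, and Cspg4, the pericyte proteoglycan NG2, 10.4-fold lower. The muscle markers and the Lars2 share lay lower in the same null libraries.

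Among adhesion genes, 1 of 20 tested kindlin, talin and integrin-linked adaptors rose and 2 fell (2 and 7 when adjusted over the list alone). The median was -0.62 (camera adjusted p = 0.00237, adjusted p = 0.452 with an estimated correlation). With the trend on transcript length and GC content removed, the adaptor median was -0.41, and that of the integrin subunits was 0.09 in place of -0.18. The muscle markers (median -3.31) and the Lars2 and mitochondrial ribosomal RNA shares were lower in the same null libraries. Fermt1, the deleted gene, belongs to this list, so part of the list's decrease was set by the knockout. The list was not tested without Fermt1. The camera call was lost without wild-type library 2 (adjusted p = 0.051) and with all libraries thinned to equal depth (0.108). Besides Fermt1, Tns1 (tensin 1) fell by 1.43 on the log2 scale, and Fermt2 rose (1.08). Tns1 lost its call without wild-type libraries 1 and 2 and null libraries 1 and 2 (highest edgeR adjusted p = 0.0937), and Fermt2 without 5 of the 6 libraries, all but null library 2 (highest 0.129). With the wild-type pair of a shared mouse number summed both lost their calls (edgeR adjusted p = 0.0527 and 0.0711), and Fermt2 did with both pairs summed (0.0889). Of 15 integrin subunits 1 fell (2 when adjusted over the list alone; median -0.18, camera adjusted p = 0.148), Itga5 of the fibronectin receptor (-0.93, edgeR adjusted p = 0.0494), a call lost with any 1 of the 6 libraries left out (highest 0.178) and with both pairs (0.172) or the wild-type pair (0.0606) summed.

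Among signalling target lists, 1 of 24 YAP/TEAD targets rose and 4 fell (2 and 6 when adjusted over the list alone; median -0.3, camera adjusted p = 0.0482, adjusted p = 0.408 with an estimated correlation). The muscle markers (median -3.31) and the Lars2 and mitochondrial ribosomal RNA shares lay lower in the same null libraries. The list call was lost without wild-type library 1 (camera adjusted p = 0.0638), 2 (0.111) or 3 (0.0506), with RLE scaling (0.0501) and with libraries of a mouse number summed in both groups (0.133) or in wild type alone (0.109). Ccn2, connective tissue growth factor, fell by 1.96 on the log2 scale, a call lost without wild-type library 3 and null library 1 (highest edgeR adjusted p = 0.0959) and with mouse number as a random effect (limma-voom, 0.249), and Tgfb2 rose from 18.6 ± 2.36 to 57.4 ± 3.35 CPM. Of 27 TGF-beta and SMAD targets 1 rose and 4 fell (1 and 5 when adjusted over the list alone; median -0.03, camera adjusted p = 0.168). Of 19 Wnt/beta-catenin targets 2 rose and 3 fell (2 and 3 when adjusted over the list alone; camera adjusted p = 0.501). Notum, a secreted Wnt inhibitor, rose 17-fold from 9.17 ± 2.7 to 133 ± 15.6 CPM (SD, n = 3; edgeR adjusted p = 6.03e-05), and the Wnt inhibitor Apcdd1 rose 9.13-fold (log2 fold change 3.19, or 2.35 without wild-type library 3 and 4.3 without wild-type library 1). The ligand Wnt10b fell 6-fold and Nkd2, a Wnt antagonist, fell 3.85-fold. Sfrp2, a secreted Wnt modulator chosen after its values were seen, fell 6.87-fold from 53.75 ± 46.25 to 5.853 ± 2.188 CPM (edgeR adjusted p = 0.024), a call lost without wild-type library 1 and null libraries 1 and 3 (highest 0.0937), with a log2 fold change of -3.44 in place of -2.78 without wild-type library 3. With mouse number as a random effect the Sfrp2 call was lost (-1.32, limma-voom adjusted p = 0.112). Of 25 NF-kB and inflammatory cytokine genes 4 rose and 1 fell (5 and 2 when adjusted over the list alone; median 0.13, camera adjusted p = 0.501). Ptgs2, the inducible cyclooxygenase, rose 14.2-fold to 127 ± 90.2 CPM, a call lost without wild-type library 3 (edgeR adjusted p = 0.157) and with mouse number as a random effect (limma-voom, 0.121), and its log2 fold change was 3.16 in place of 3.83 without null library 1. None of 34 type I interferon genes passed (0 also when adjusted over the list alone; median 0.26, camera adjusted p = 0.278). Of 22 antigen presentation genes 2 fell (2 when adjusted over the list alone; median -0.36, camera adjusted p = 0.114), and that list passed without wild-type library 3 (camera adjusted p = 0.0343).

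The lists of oxidative phosphorylation, unfolded protein and integrated stress response, NRF2 and hypoxia genes passed camera as higher in null tumours by small amounts, in the libraries with lower muscle marker CPM and a lower Lars2 share. All 4 calls were lost with an estimated correlation (camera adjusted p = 0.481, 0.408, 0.481 and 0.481). The glycolysis and cholesterol lists did not pass. Of 45 oxidative phosphorylation genes 2 rose and 0 fell (1 and 0 when adjusted over the list alone), while 41 had a log2 fold change above 0, with a median of 0.5 (camera adjusted p = 2.42e-05, adjusted p = 0.481 with an estimated correlation). Ndufb8 and Cox7a2, subunits of the respiratory chain, stood at 1.26 and 1.09 and lost their calls without wild-type library 2 or 3 and null library 1 or 3, and Cox7a2 also without null library 2 (highest edgeR adjusted p 0.104 and 0.131). Both also lost their calls with both pairs of a shared mouse number summed (edgeR adjusted p = 0.0631 and 0.128) and with the wild-type pair summed (0.0606 and 0.0827). Of 24 genes of the unfolded protein and integrated stress response 3 rose (3 when adjusted over the list alone; median 0.52, camera adjusted p = 0.00116, adjusted p = 0.408 with an estimated correlation). Psat1, an enzyme of serine synthesis, rose 3.02-fold from 46 ± 2.61 to 142 ± 9.47 CPM. Of 23 NRF2 and oxidative stress genes 3 rose (3 when adjusted over the list alone; median 0.58, camera adjusted p = 0.00209, adjusted p = 0.481 with an estimated correlation), among them the aldehyde dehydrogenase Aldh3a1 at 6.33-fold (log2 fold change 2.66, or 2.07 without wild-type library 3). Of 32 hypoxia response genes 4 rose and 1 fell (10 and 2 when adjusted over the list alone; median 0.31, camera adjusted p = 0.0328, adjusted p = 0.481 with an estimated correlation). The hypoxia list call was lost without wild-type library 1 (camera adjusted p = 0.265), wild-type library 2 (0.051) or null library 1 (0.192), and with the wild-type pair of a shared mouse number summed (0.0544). Ddit4, a stress-induced inhibitor of mTORC1 signalling, rose 6.52-fold to 62.7 ± 27.3 CPM, a call lost without wild-type library 3 and null library 1 (highest edgeR adjusted p = 0.11). Its log2 fold change of 2.71 was 1.75 without wild-type library 3 and 3.71 without wild-type library 1.

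The remaining lists did not pass. Of 23 glycolysis genes 1 rose (2 when adjusted over the list alone; median 0.15, camera adjusted p = 0.35), the lactate transporter gene Slc16a1 (1.45), whose call was lost without null library 1 (edgeR adjusted p = 0.0521). Of 39 cell cycle and mitosis genes 1 fell (1 when adjusted over the list alone; median 0.19, camera adjusted p = 0.126). That gene was Mki67, which encodes the proliferation antigen Ki-67 and fell 2.38-fold from 287 ± 40.8 to 120 ± 40.5 CPM, a call lost without wild-type libraries 2 and 3 and null libraries 1 and 3 (highest edgeR adjusted p = 0.101) and with both pairs of a shared mouse number (0.0629) or the wild-type pair (0.0525) summed. None of 23 cholesterol and lipid synthesis genes passed (0 also when adjusted over the list alone; median -0.08, camera adjusted p = 0.168), and that list passed without wild-type library 3 (camera adjusted p = 0.0362), as did the macrophage and monocyte list (0.0369). Of 21 immediate early and heat shock genes 3 rose (4 rose and 1 fell when adjusted over the list alone; median 0.01, camera adjusted p = 0.607), among them Hspa1b, 3.78-fold higher, which has a near-identical copy. Of the erythroid, hair follicle and sebaceous, and melanocyte and nerve lists 2, 3 and 4 members were tested, too few for a list test. With an estimated correlation 0 of the 31 lists passed (lowest adjusted p = 0.408), where camera with the preset correlation called 12, fry called 4 for direction (skeletal muscle, T and NK cell, neutrophil, and dendritic and mast cell markers) and 22 for change in either direction. The median, the mean and the camera direction of a list differed in sign for epithelial junction genes (median 0.03, mean 0.23, lower by camera), mesenchymal transition genes (0.04, -0.13, lower), matrix proteases (0.08, 0.23, lower), Wnt targets (-0.28, 0.01, lower) and endothelial markers (0.01, -0.04, lower).

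**Figure D3:**
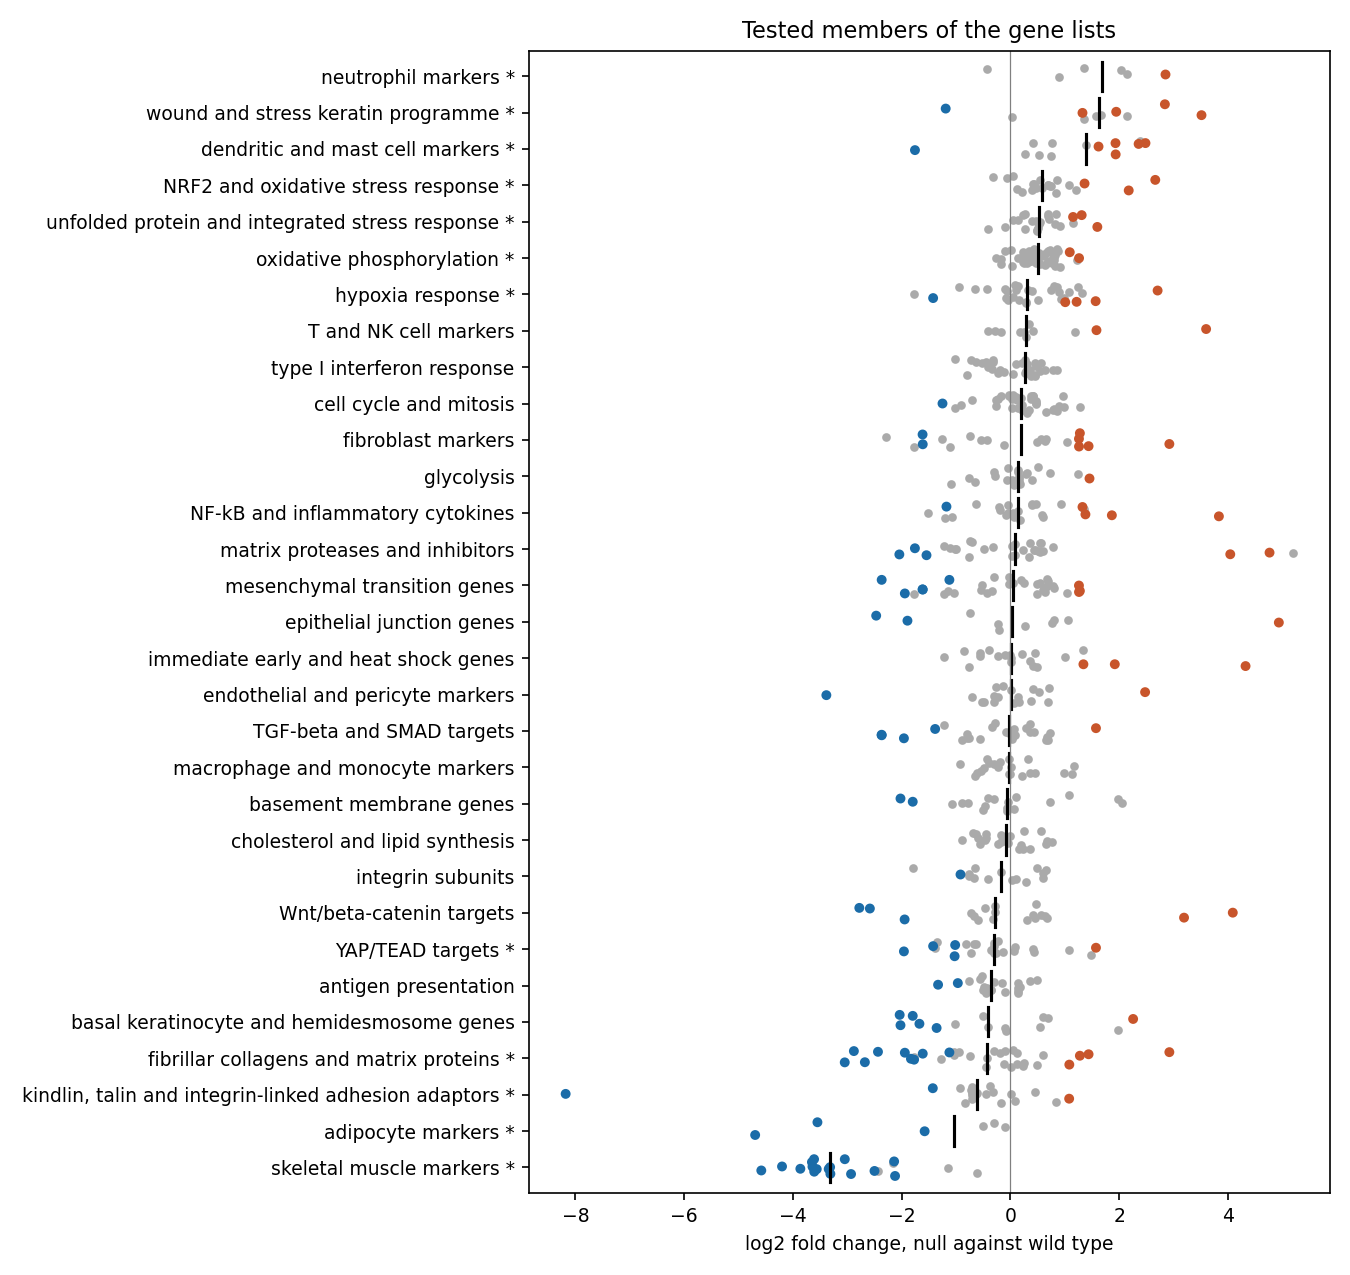
Log2 fold change, null against wild type, of every tested member of the 31 gene lists with at least 5 tested members. Points are genes, coloured where they passed the edgeR test (3 libraries per group), black bars are list medians and an asterisk marks the 12 lists that passed camera with the preset correlation; skeletal muscle markers lie lowest, with a median of -3.31.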

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

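Thinning and the depth covariates were chosen after the data were seen; all other alternatives were fixed before.

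The 688 changed genes (269 higher, 419 lower) stayed within 1.5 times under DESeq2 (718), RLE (699), upper-quartile scaling (704), no filter (842), the 10 CPM filter (538), limma-voom with quality weights (909), both libraries of each mouse number summed (484) and the wild-type pair summed (493). Higher genes under the last were 165. Of the 688 genes, 587, 682, 679, 618, 532, 558, 393 and 441 kept their call and direction in these fits, in that order, and none had the opposite sign. With mouse number as a random effect 1156 genes passed, 641 higher and 515 lower, 546 of them among the 688. The consensus correlation of libraries with a shared number was 0.597 in that fit. It used no quality weights, and each mouse number lies within 1 genotype. The larger count is therefore no evidence that the calls hold between animals. Against a fold change of 1.5, a stricter question, 207 passed (74 and 133). At equal depth, with 4330 genes left to test, 128 passed (48 and 80). With log10 of the library total as a covariate 2436 passed (1210 and 1226), and with a depth class 2122 (1039 and 1083), where 684 and 676 of the 688 genes kept their call and direction; the cause of the larger counts was not tested. Leaving out 1 library gave 179 to 855 genes, 59 to 421 higher and 120 to 434 lower. Fermt1 ranged from -8.99 to -6.57 in these fits and from -9.11 to -6.73 under the others, passing in each; at equal depth it had too few reads to be tested. No paired analysis was possible because the mouse numbers do not cross the groups. The pseudocount alternative was not run, since the files hold counts. DESeq2, limma-voom, the random effect, the fold threshold and the depth covariates were not run for the list test, which works on log2 CPM.

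Gene lists passing numbered 12, and 9 to 14 with 1 library left out, 10 to 13 under the other scalings, filters and summed fits, 6 at equal depth, 0 with an estimated correlation and 4 by fry for direction. At equal depth the Wnt/beta-catenin list changed direction and passed (adjusted p = 0.0203), with fewer genes tested; the cause was not tested. Over all alternatives, results for named genes stayed on their side of the threshold in 2297 cases, lost the call in 322 and gained it in 108. Direction was compared only where the main or the alternative fit called the result, and it changed in 0 cases. Of the losses 24 came with both pairs of a shared mouse number summed, 22 with the wild-type pair summed and 22 with the random effect. For lists these numbers were 410, 35, 7 and 1. The 1 change of direction was that of the Wnt/beta-catenin list, which the main test had not called. Depth limits wild-type library 2 most, where 3 counts equal 18.6 CPM.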

Other observations

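Of the tests below, the second muscle list and the length and GC check were set before their results were seen; the depth test, the granzyme tests and the split count were chosen after. The second muscle list was itself written after muscle genes were seen to fall.

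Granzyme genes outside the named rule, chosen after their values were seen, also rose in null tumours. Gzmf rose 18.1-fold from 27.5 ± 10.2 to 421 ± 122 CPM, Gzmd rose 16.7-fold from 28.1 ± 16.6 to 350 ± 127 CPM and Gzmc rose 2.99-fold from 52.1 ± 27.8 to 167 ± 10.7 CPM (SD, n = 3; edgeR adjusted p = 0.000125, 0.000845 and 0.0135). The Gzmc call was lost without null library 1 (edgeR adjusted p = 0.0621), and without wild-type library 3 the log2 fold change of Gzmd was 3.37 in place of 4.06. Of further small proteoglycans, also chosen after their values were seen, decorin (Dcn) rose 2.71-fold from 1200 ± 390 to 3243 ± 359 CPM (edgeR adjusted p = 0.0255), whereas biglycan (Bgn) fell 6.39-fold from 523.9 ± 198.3 to 78.27 ± 64.75 CPM (edgeR adjusted p = 0.0118). The Dcn call was lost without wild-type library 2 and null libraries 1 and 3 (highest edgeR adjusted p = 0.0887) and with both pairs of a shared mouse number (0.092) or the wild-type pair (0.0607) summed. The Bgn call was lost without wild-type library 3 and null library 1 (highest edgeR adjusted p = 0.0654) and with mouse number as a random effect (limma-voom, 0.169). Without null library 2 the log2 fold change of Bgn was -3.65 in place of -2.68. Of T cell receptor complex genes, Cd3e had 1 and 3 reads in total in wild-type and null tumours and Trac 0 and 1, Cd3d had 21 and 51 (2.94 ± 2.78 and 1.65 ± 1.01 CPM) and Cd3g 49 and 33 (5.55 ± 5.87 and 0.844 ± 0.888 CPM), while the NK receptor gene Ncr1 stood at 13.1 ± 4.67 and 14.5 ± 4.32 CPM. Among keratinocyte genes Krt5 stood at 1.41 ± 2.17 and 0.184 ± 0.198 CPM, Krt14 at 36.2 ± 9.49 and 8.6 ± 3.03 CPM, Trp63 at 15 ± 9.06 and 22.9 ± 4.17 CPM and Cdh1 at 4.18 ± 1.84 and 5.5 ± 1.69 CPM, beside Vim at 3190 ± 1950 and 4980 ± 211 CPM.

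The lower muscle genes of null tumours may reflect skeletal muscle taken along with the wild-type tumours, as a hypothesis. A second list of 31 muscle genes had 13 tested members, all 13 below 0 and 8 called lower. Their median log2 fold change was -2.23 (SE over genes 0.36), past the bound set beforehand for admixed muscle, but by less than this SE. Muscle invaded by the tumours, or muscle genes expressed by tumour cells, could lower the same genes. The second list cannot tell these apart. Depth was first examined by thinning, which left 4 markers (median -2.94) and decided nothing; the covariate test that replaced it was chosen after the fit with that covariate had been seen to keep nearly all calls. In it the marker median was -3.11 (SE over genes 0.3). Since 684 of the 688 calls were already known to hold in that fit, this result was largely set in advance. It does not decide on depth. Whether muscle was dissected with the tumours, invaded by them or expressed by tumour cells was not tested.

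The rise of granzymes and perforin in null tumours was set against more NK or T cells, reads shared between copies and a change of the whole chromosome stretch. Genes of NK and T cell identity had a median of 0.29 (15 tested, 0 called by edgeR, median absolute deviation 0.44). The set also held Ptprc (0.07), a gene of leukocytes in general and not of these cells alone. The median was 3.83 for 8 granzyme and perforin genes, of which 7 rose (Gzmb stood at 1.19, edgeR adjusted p = 0.0687). Several of these 8 were picked because they rose, so the gap between the medians was partly set in advance. In group means, the identity genes other than Ptprc and Il18rap lay under the floor of wild-type library 2 (18.6 CPM). The set ranged from -0.5 (Il18rap) to 1.3 (Klrd1). The identity genes thus showed no shared rise, but the comparison cannot decide on cell number. Granzymes D to G summed to 66.6 ± 27.1 and 1180 ± 428 CPM, a ratio of 17.7, so sharing among these copies does not account for it. The 25 tested genes on each side of the cluster had a median of 0.35 (SE over genes 0.11) against 4.06 inside it. There 9 of 11 tested genes rose, mast cell proteases among them. A higher output of these genes per cell, in NK cells or in other cells, remains a candidate explanation that was not tested.

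Oxidative phosphorylation genes lay slightly higher in null tumours (median 0.5, SE over genes 0.07). Only 2 of 45 passed singly, and the list did not pass camera with an estimated correlation (adjusted p = 0.481). After the trend on transcript length and GC content was removed the median was 0.4, above the 95th percentile of 10000 random lists matched on expression. This argues against that trend as the whole cause of the median in these libraries. The random lists do not keep the correlation among the list's genes (estimated at 0.343), so the percentile does not measure variation between tumours. The same removal was applied to the other lists, which the check set beforehand did not cover. The medians moved from -0.44 to -0.3 for matrix genes, from -0.42 to -0.1 for basal keratinocyte genes and from -0.28 to 0.15 for Wnt targets. Those of YAP/TEAD targets (-0.3 to -0.26) and skeletal muscle markers (-3.31 to -3.19) moved less. RNA quality, for which the Lars2 and mitochondrial ribosomal RNA shares may stand, goes with genotype here and was not tested.

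Among the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 688 genes or more, and the highest of the others gave 1 gene. Of these splits 2 keep libraries of a shared mouse number together, the real one and 1 that gave 0 genes. With 10 splits the share cannot go under 0.1, and the 2 that keep shared numbers together are too few to judge by. Every split but the real one puts both genotypes on each side. A difference between genotypes then adds spread within the sides and lowers the count. The split count therefore leaves chance open.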
